A study of Mus musculus with 6 samples.

How the data were processed

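RNA of 6 cultures of the mouse osteosarcoma line mOS482, 3 labelled scrambled shRNA and 3 labelled Sox2 shRNA, had been hybridised by the authors to 1-colour Affymetrix mouse genome arrays, 1 array per culture, per the labels' protocols. The labels describe triplicate plates of stably infected, hygromycin-selected cells, so that the replicates were plates of 1 line per hairpin. P-values therefore measure the spread between plates and arrays and not between independently derived lines. The authors read the arrays with GCOS 1.4 and used RMA, per the submitters' processing notes. The RMA version and settings are not given in the sources used here. Both deposited tables held the same values, with 0 cells differing between them, on a log scale that was taken as log2 because RMA returns log2 values. The log base is not stated. The deposited log2 values had been centred per probe set close to the scrambled arrays, as seen in the values themselves. The medians over probe sets were 0.0027, 0 and -0.0029 in scrambled arrays 1 to 3, and 0.071, 0.043 and 0.033 in Sox2 shRNA arrays 1 to 3. Scrambled array 2 was exactly 0 in 37.5% of probe sets and no other array in more than 0.071%. The set of arrays used for the centring is not given in the sources used here. Centring leaves differences between arrays as they were, but removes the level of each probe set, so that signal over background is unknown here for every gene. The number of arrays limits the precision.

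Of the 22690 probe sets, 64 were array controls and were left out of the gene tests. Of all probe sets, 21569 named 1 gene, 578 named several and 543 named none. The 21556 probe sets that named 1 gene and were not controls were used, and 21181 of them were matched by Entrez number to RefSeq names, which updated 1735 symbols. Chromosomes and positions are those of the deposited table, whose genome build is not stated. The probe sets of a gene were averaged, which gave 13213 genes, 5219 of them with more than 1 probe set. A probe set with the highest mean per gene had been planned for this step, but on centred values that rule favours probe sets that are higher in the arrays labelled Sox2 shRNA, so averaging, foreseen as an alternative, was used in its place. That exchange was made after the values were seen to be centred, and the highest mean was run as an alternative. The largest variance favours probe sets that differ between the groups in the same way.

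The groups were compared with limma 3.58.1 (lmFit and eBayes, R 4.3.3) on the log2 values of all 6 arrays without covariates, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. A second count added a log2 difference of at least 1 in size, which is 2-fold. Differences are Sox2 shRNA minus scrambled shRNA, on the log2 scale, with the SE of limma and n = 3 arrays per group. Single values such as the array control measures were compared with a two-sided exact permutation test, which cannot go below p = 0.1 with 3 arrays against 3. Lists of genes, 34 in all, were fixed before the data were examined and tested with limma's camera at its preset correlation of 0.01, with adjustment over the lists. Camera with an estimated correlation and fry were also run. Gene ontology terms paired with probe sets in the deposited table, of 10 to 300 measured genes, were tested with a one-sided Fisher's exact test among the genes changed at least 2-fold, higher and lower apart, against the 12198 genes with a term.

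The genes named were chosen by a rule set before the data were examined. It took Sox2, then the 12 largest rises and the 12 largest falls among genes with an adjusted p under 0.05, a log2 difference of at least 1 in size and groups that did not overlap, leaving out symbols of the Gm-number kind or ending in Rik. It also took up to 4 members of each list by smallest adjusted p, and Nf2, Wwc1, Yap1, Ccn1, Ccn2, Ly6a, Runx2 and Alpl. A gene named outside that rule is said to have been chosen after its values were seen. The alternatives tried were the replicate number as a block, the other deposited table, median centring of each array, 3 other rules for probe sets, another variance model, array weights, other thresholds, other set tests and each array left out in turn. A covariate for the spike-in level and a fit without X-linked genes were added after seeing the data. The scripts were tested on simulated data with the residual spreads of these arrays, where 200 of the 13213 genes were changed. In that simulation limma recovered 44% of 50 genes changed by 0.5 on the log2 scale, 80% of 50 changed by 1, 96% of 50 changed by 2 and 100% of 50 changed by 3, and called 9 of 13013 unchanged genes. The simulated noise was equal in all arrays, and far fewer genes were changed than the 38.5% called in the real data. These rates need not hold for the real comparison. Figures were drawn with matplotlib 3.10.9.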

Results

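Gene expression was measured on 6 arrays in mOS482, a mouse osteosarcoma line from a spontaneous tumour that arose without Rb and p53. The cells stably expressed either a scrambled hairpin, on 3 arrays, or a hairpin against Sox2, on 3 arrays. Sox2 is a transcription factor of pluripotent and tissue stem cells, and the series asks what its depletion changes in osteosarcoma cells with stem cell properties. Values are log2 and centred per probe set, so that only differences between arrays are given, with ± for the SE of limma and n = 3 arrays per group throughout. The arrays labelled Sox2 shRNA correlated with each other over all probe sets at r = 0.910 for arrays 2 and 3, at 0.831 for arrays 1 and 2 and at 0.811 for arrays 1 and 3, a correlation across probe sets, which are not independent replicates.

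The probe set of the targeted gene was not lower in the arrays labelled Sox2 shRNA. Sox2 has 1 probe set, aligned to chromosome 3 from 34548919 to 34551380 on the plus strand (build not stated), and its log2 difference was 0.27 ± 0.14 (limma adjusted p = 0.154). The values were 0.17, 0.055 and 0.58 in the arrays labelled Sox2 shRNA and 0.069, -0.039 and -0.033 in the scrambled arrays. Whether this probe set lay above background is unknown, because the levels had been removed. The arrays therefore showed no fall of Sox2, but a probe set at background could not show one. They do not decide whether Sox2 was depleted. Every direction given here is that of the arrays labelled Sox2 shRNA, whatever their Sox2 level. No other pluripotency factor was called lower either, but whether their probe sets lay above background is unknown as well. The median difference of these factors was 0.45 in Sox2 shRNA array 1 and 0.15 in arrays 2 and 3. With the spike-in level as a covariate it was 0.022. Of the 12 measured, 3 rose and 0 fell (Dppa5a 0.53 ± 0.11, Klf4 0.56 ± 0.14 and Sall4 0.32 ± 0.094), with 3 and 0 adjusted over the list alone and a camera adjusted p = 0.0976 for the list (0.522 with an estimated correlation), and Lin28a differed by 0.30 with an adjusted p = 0.0965. Without any 1 scrambled array, or without Sox2 shRNA array 2, 1 pluripotency gene rose. Dppa5a (0.50) and Sall4 (0.13) were not called with the spike-in level as a covariate, under which Lin28a was at -0.083, and Lin28a was called without Sox2 shRNA array 3 (0.40).

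The largest rises in the arrays labelled Sox2 shRNA included those of secreted matrix, protease and immune genes. Efemp1, an extracellular matrix glycoprotein, was 103-fold higher (6.69 ± 0.12 on the log2 scale, limma adjusted p = 2.5e-07), the protease inhibitor Serpine2 65.0-fold (6.02 ± 0.14), the metalloproteinase Mmp3 58.5-fold (5.87 ± 0.17) and the proteoglycan decorin, Dcn, 54.7-fold (5.77 ± 0.15). Next came Mmp10 (5.13), complement component C3 (5.03), the interferon-induced genes Ifi44 (5.01), Oas1a (4.83) and Usp18 (4.71), the collagenase Mmp13 (4.62), the chemokine Ccl17 (4.58) and the BMP antagonist Grem1 (4.25). The largest falls were those of the ribosomal protein paralogue Rpl39l (-6.64 ± 0.34), of Xist, the RNA that coats the inactive X chromosome (-5.94 ± 0.16, limma adjusted p = 4.7e-07), of the exon junction complex gene Magohb (-5.05 ± 0.11) and of the homeobox gene Rhox5 (-4.92 ± 0.17). The 3 probe sets of Xist differed by -5.08 to -6.74. The transcription factors Zic1 (-3.52) and Dlx5 (-2.69), the proteoglycan biglycan, Bgn (-3.47), the matrix protein Tgfbi (-2.81), the heat shock gene Hspa1b (-2.62), Mmp23 (-2.22), AW209491 (-2.19) and the anthrax toxin receptor Antxr2 (-2.15 ± 0.38) followed, the last not called with the spike-in level as a covariate (-0.72, adjusted p = 0.224).

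**Figure D1:**
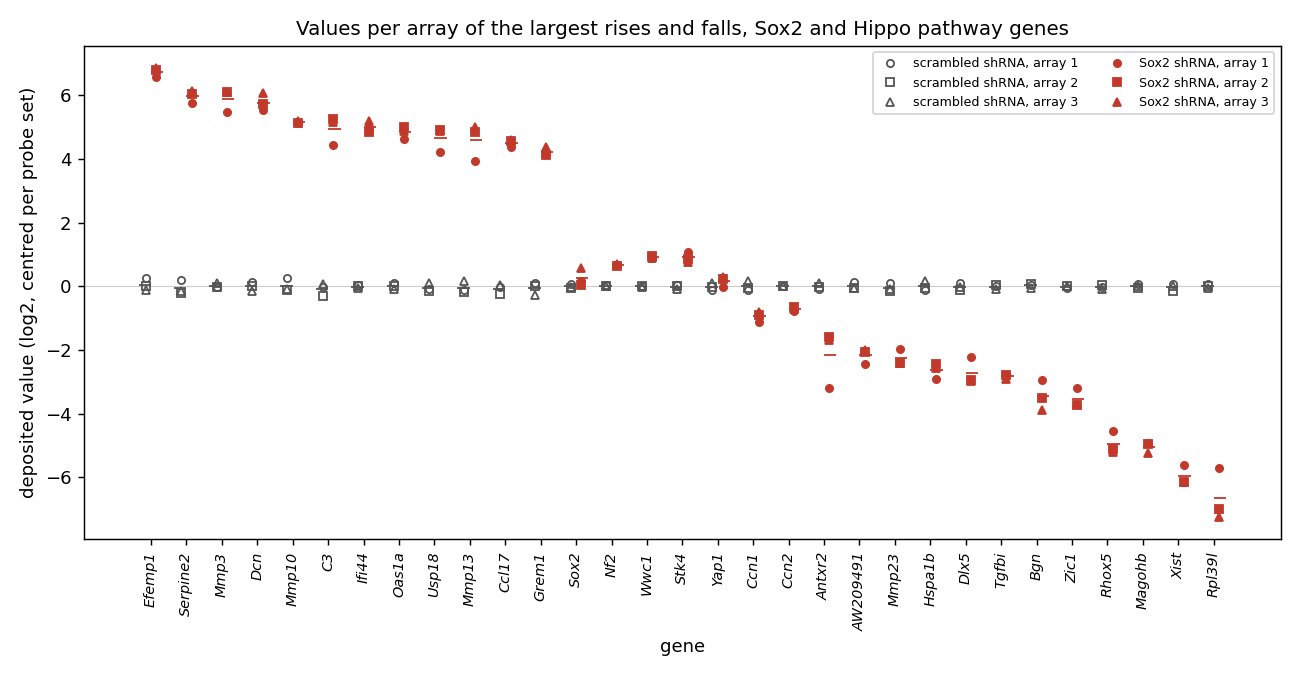
Deposited log2 value, centred per probe set and averaged over the probe sets of a gene (y axis), of each array for 31 genes (x axis), namely the 12 largest rises, Sox2, 6 genes of the Hippo pathway and its output, and the 12 largest falls. Open grey symbols are scrambled arrays, filled red symbols arrays labelled Sox2 shRNA, and short lines group means over 3 arrays. The scrambled arrays lie near 0, the means of the arrays labelled Sox2 shRNA differ from theirs by 6.69 for Efemp1 to -6.64 for Rpl39l, and Sox2 differs by 0.27.

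Across the 13213 genes tested, limma called 2216 higher and 2874 lower in the arrays labelled Sox2 shRNA, 38.5% of the genes. Of these, 354 higher and 478 lower genes differed at least 2-fold, and 96 higher and 21 lower genes at least 4-fold. The groups did not overlap in 7513 genes, or 56.9%, where chance gives 10% per gene over all splits. A shift shared by the genes of an array would also raise that share. The median difference of all genes was 0.078. The number of higher genes depended on each scrambled array, at 1331, 1297 and 1155 without scrambled array 1, 2 or 3, while the 2-fold counts stayed between 342 and 369 higher and between 362 and 563 lower over all 6 arrays left out in turn. Under the first planned rule, the probe set of highest mean per gene, limma called 2512 higher and 1900 lower genes, 504 and 406 of them at least 2-fold. Of the genes named here and called under both rules, that rule put Tgfbi (-1.34), Mmp23 (-1.17) and Hmgcs1 (-0.44) closer to 0 by over 1.5 times. It put Wwc1 (2.06), Lpl (3.63), Dgat2 (1.11), Col11a1 (1.30), Sox9 (0.46), Vcam1 (2.79), Trp53inp1 (0.84), Srxn1 (1.87), Acta2 (2.75), Csf1r (1.35) and Flt1 (0.71) as much farther from it.

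Genes of the interferon response rose together in the arrays labelled Sox2 shRNA. Of the 22 measured genes of that list, 21 rose and 0 fell (22 and 0 adjusted over the list alone), 18 of them at least 2-fold, with a median difference of 2.30. The antiviral effector Ifit1 rose by 4.15 ± 0.087 and Ifih1, a sensor of double-stranded RNA, by 3.42 ± 0.084, beside Ifi44 and Oas1a above. The camera adjusted p was 3.7e-16, and 0.19 with an estimated correlation. Chemokines and NF-kB targets rose as well, 10 of 17 genes with 1 fall (median 0.63; 12 and 1 adjusted over the list alone), among them Cxcl12 (2.76 ± 0.19), interleukin 6, Il6 (2.71 ± 0.21), Ccl5 (2.63 ± 0.14) and Ccl7 (2.35 ± 0.091). The camera adjusted p of that list was 6.8e-05, and the adjusted p was 0.522 with an estimated correlation. Of 11 genes of antigen presentation by MHC class I, 7 rose and 0 fell (median 0.51; 7 and 0 adjusted over the list alone; camera adjusted p = 0.018; adjusted p = 0.522 with an estimated correlation). They included the immunoproteasome subunits Psmb8 (1.84 ± 0.20) and Psmb9 (0.68 ± 0.099), H2-D1 (0.51 ± 0.081) and B2m (1.09 ± 0.18), and Psmb9 was not called with the spike-in covariate (0.52, limma adjusted p = 0.0754).

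Mitotic genes and genes of cholesterol synthesis fell. Of 21 measured genes of mitosis, 18 fell and 0 rose (18 and 0 adjusted over the list alone), 7 of them at least 2-fold, with a median of -0.73. The cyclin-dependent kinase Cdk1 fell by 1.62, Ube2c by 1.20, Cdc20 by 0.79 and cyclin B1, Ccnb1, by 0.73, with SEs of 0.13, 0.15, 0.086 and 0.088. The camera adjusted p was 2.5e-06, and 0.522 with an estimated correlation. With the spike-in level as a covariate, 5 mitosis genes were lower, with a median of -0.40. Of 21 genes of DNA replication and the G1/S step, 10 fell and 0 rose (11 and 0 adjusted over the list alone; median -0.36; camera adjusted p = 0.0015; adjusted p = 0.522 with an estimated correlation), such as Ccne2 (-1.51 ± 0.27), Slbp (-0.78 ± 0.14), Rrm2 (-0.75 ± 0.11) and Pola1 (-0.58 ± 0.090). That call was lost with that covariate (0 genes lower, median -0.053, adjusted p = 0.665), which was chosen after seeing the data, and with the first planned rule of the highest mean per gene (median -0.018, adjusted p = 0.10), and 6 genes were lower without scrambled array 2 or 3. Of 16 genes of cholesterol synthesis, 13 fell and 0 rose (13 and 0 adjusted over the list alone), with a median of -0.63, a camera adjusted p = 8.6e-06 and an adjusted p = 0.26 with an estimated correlation. Under the first planned rule of the highest mean the median was -0.12 and the camera adjusted p = 0.016, and Cyp51 was not called (-0.18). Idi1 fell by 1.42 (SE 0.16), Sqle, which makes squalene epoxide, by 1.05 (SE 0.10), Hmgcs1 by 1.05 (SE 0.10) and Cyp51 by 0.83 (SE 0.084). The spike-in probe sets were 0.84 higher in the arrays labelled Sox2 shRNA beside these lists (below, with the other array controls).

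The Hippo pathway, a kinase cascade that restrains the coactivator YAP, was among the lists fixed before the data were examined. Its upstream members Nf2 (0.67 ± 0.076, limma adjusted p = 4.6e-04) and Wwc1 (0.91 ± 0.076, adjusted p = 1.2e-04) and the kinase Stk4 (0.92 ± 0.10) rose, and the scaffold Ajuba fell (-1.22 ± 0.16). The 4 probe sets of Nf2 lay between 0.29 and 0.90 and those of Wwc1 between -0.042 and 2.06, so that the Wwc1 probe sets disagreed. Of 18 measured pathway components 3 rose and 7 fell (4 and 7 adjusted over the list alone), with a median of -0.085 and a camera adjusted p = 0.378. These counts and the median pool transcripts of all members, whatever their role in the pathway, and give no direction of its activity. The median rested on Sox2 shRNA array 1, without which it was -0.0060 with 4 rises and 8 falls, and with the spike-in covariate 3 rose and 1 fell. Under the first planned rule of the highest mean it turned to 0.11. Yap1 itself differed by 0.16 ± 0.11 (adjusted p = 0.263), but was called higher without Sox2 shRNA array 1 (0.26, adjusted p = 0.0423) and with the spike-in covariate (0.52, adjusted p = 0.0391). Of the 6 YAP, TAZ and TEAD factors 2 rose, Tead2 (0.86 ± 0.095) and Tead4 (0.51 ± 0.12), and 1 fell, Wwtr1, which encodes TAZ (-0.37 ± 0.10), with a camera adjusted p = 0.403 (2 and 1 adjusted over the list alone). Wwtr1, with probe sets from -0.85 to -0.090, was not called without scrambled array 1, 2 or 3 (limma adjusted p = 0.083, 0.060 and 0.078), without Sox2 shRNA array 2 (0.054), with the highest mean (-0.090) or with the spike-in covariate (-0.24). The factors that rose came to 1 without scrambled array 1 or 3, when Tead4 was not called. YAP/TAZ target genes split, with 6 higher and 6 lower of 19 (8 and 7 adjusted over the list alone; median 0.23, with 0.13 without Sox2 shRNA array 2 and 0.075 without _x_at and _s_at probe sets; camera adjusted p = 0.942). The secreted matricellular genes Ccn1 (-0.95 ± 0.12) and Ccn2 (-0.72 ± 0.080) and the transcription factor Foxf2 (-1.39 ± 0.12) fell, and Igfbp3 rose by 4.02 ± 0.21. Ccn2 lies on chromosome 10, where 77.3% of the changed genes were lower (below).

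**Figure D2:**
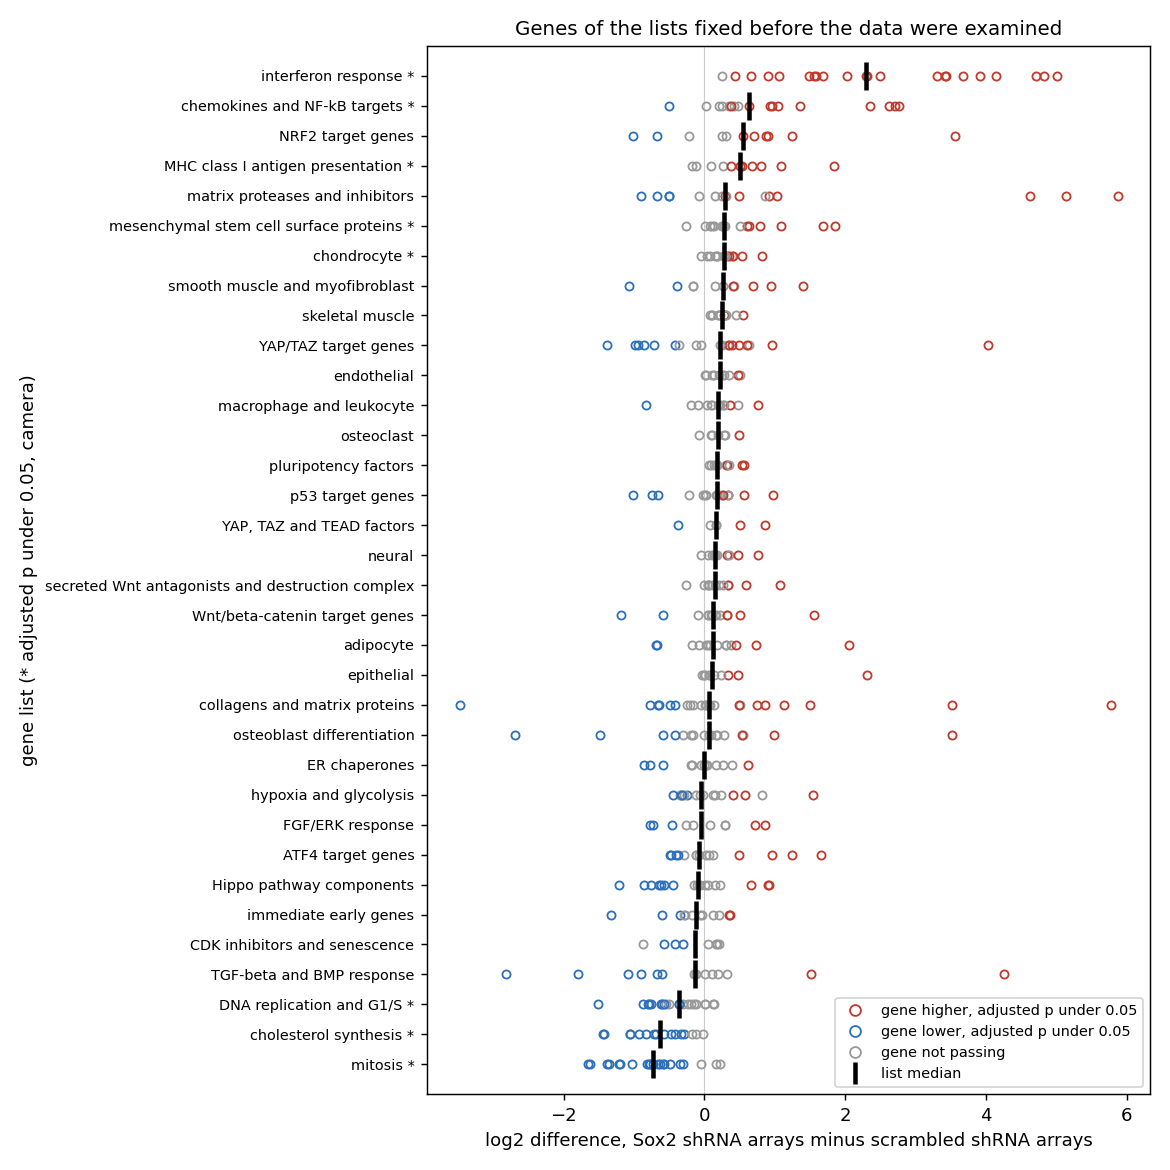
Log2 difference, Sox2 shRNA arrays minus scrambled arrays with n = 3 per group (x axis), of each measured gene of the 34 lists fixed before the data were examined (y axis, ordered by list median). Red circles are genes that rose, blue circles genes that fell and grey circles genes that did not pass the limma threshold of 0.05, black bars are list medians, and asterisks mark the 8 lists that passed camera at its preset correlation. The 9 other splits of the 6 arrays each keep a part of the difference between the groups. In them camera called 3 to 8 lists, with as many as 8 in 1 split. The medians run from -0.73 for mitosis to 2.30 for the interferon response.

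Surface proteins of mesenchymal stem cells rose, 6 of 17 with 0 falls (10 and 1 adjusted over the list alone; median 0.28). They included Ly6a, the stem cell antigen Sca-1 (1.69 ± 0.093), the adhesion molecules Vcam1 (1.86 ± 0.11) and Mcam (1.09 ± 0.12), and the receptor Pdgfra (0.79 ± 0.090). The camera adjusted p was 0.0025, and 0.26 with an estimated correlation. Osteoblast genes went both ways, with 3 higher and 4 lower of 17, also when adjusted over the list alone (median 0.060, mean 0.032, while camera put the list on the lower side of other genes with an adjusted p = 0.942). That median turned to -0.026, -0.0067 and -0.0027 without Sox2 shRNA array 1, Sox2 shRNA array 3 or scrambled array 2. Collagen type I alpha 1, Col1a1, rose by 3.52 ± 0.096 and alkaline phosphatase, Alpl, by 0.99 ± 0.12, while Dlx5 and the endopeptidase Phex (-1.48 ± 0.095) fell. The 2 probe sets of Phex, on chromosome X, disagreed, at -3.24 and 0.29, the latter being its value with the highest mean. Runx2, the master regulator of osteoblasts, differed by -0.16 ± 0.089 (adjusted p = 0.186), with probe sets between -1.19 and 0.70, and it was called lower with the probe set of largest variance (-1.19, adjusted p = 1.6e-04) and differed by 0.70 with that of highest mean (adjusted p = 0.0612). Of 15 chondrocyte genes 6 rose and 0 fell (median 0.28; 6 and 0 adjusted over the list alone), led by Col11a1 (0.82 ± 0.086), with Col9a1 (0.53 ± 0.12), Comp (0.35 ± 0.084) and Sox9 (0.28 ± 0.075). The camera adjusted p of the chondrocyte list was 0.033 (adjusted p = 0.522 with an estimated correlation), and the call was lost without Sox2 shRNA array 1 (median 0.13, adjusted p = 0.088) and without scrambled array 1 or 2 (adjusted p = 0.0512 for both), as well as with array weights (0.074), the probe set of highest mean (0.17) and the spike-in covariate (0.507). The rises came to 1, 2 and 2 without scrambled array 1, 2 or 3, and Sox9 and Col9a1 were not called with the spike-in covariate. Among 14 adipocyte genes 3 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.44). Lipoprotein lipase, Lpl, rose by 2.05 ± 0.096 and Dgat2 by 0.73 ± 0.11, and Cd36 (-0.69 ± 0.11) and Pparg (-0.68 ± 0.13) fell. Cd36, with probe sets from -1.22 to -0.20, was not called with the highest mean (-0.20, limma adjusted p = 0.186), and Pparg was not called with the spike-in covariate (-0.52, adjusted p = 0.181).

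Extracellular matrix genes changed in both directions. Of 16 matrix proteases and inhibitors 7 rose and 4 fell (10 and 4 adjusted over the list alone; median 0.30; camera adjusted p = 0.0976, but 0.0064 with the spike-in covariate and 0.038 without X-linked genes), with the gelatinase Mmp2 (1.03 ± 0.12) beside Mmp3, Mmp10 and Mmp13. Of 25 collagens and matrix proteins 7 rose and 6 fell (8 and 6 adjusted over the list alone; camera adjusted p = 0.673), and decorin rose while biglycan, the related small proteoglycan, fell. Biglycan is X-linked, and of 424 X-linked genes 60 were at least 2-fold lower and 5 at least 2-fold higher. Col6a2 rose 2.82-fold. Among 14 genes of the TGF-beta and BMP response 2 rose, Grem1 and Ltbp2 (1.51 ± 0.13), and 6 fell, including the inhibitor Smad6 (-1.79 ± 0.11) and Tgfbi (2 and 6 adjusted over the list alone; camera adjusted p = 0.24). Among 11 smooth muscle and myofibroblast genes 4 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.354). The falls came to 0 without scrambled array 1 or 3 and to 1 without scrambled array 2 or Sox2 shRNA array 3. Acta2 (1.40 ± 0.092, with probe sets at 0.063 and 2.75), Tagln (0.94 ± 0.16), Tpm2 (0.69 ± 0.096) and Lmod1 (0.41 ± 0.097) made up the rises. Acta2 was not called without _x_at and _s_at probe sets (0.063), Lmod1 without scrambled array 1 or 2, and Tpm2 with the spike-in covariate (0.44).

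Other signalling and stress lists showed single genes and no list call in the comparison of all arrays and genes without a covariate. The counts of these lists were equal when adjusted over the list alone, except for hypoxia and glycolysis (5 rises and 5 falls), immediate early genes (2 and 4), CDK inhibitors (0 and 4) and p53 targets (4 and 4). Counts this small moved with single arrays. Without Sox2 shRNA array 1, hypoxia and glycolysis gave 7 rises and 5 falls with a median of 0.032, ER chaperones 4 and 3 with a median of 0.065 and Wnt antagonists 5 and 0, and without each scrambled array the hypoxia list gave 0 falls, Wnt antagonists 1 rise and CDK inhibitors 1 fall. The FGF/ERK median turned to 0.049 and 0.061 without Sox2 shRNA array 2 or 3, with 4 rises and 4 falls in the latter case, and the ATF4 median was -0.13 without Sox2 shRNA array 2. Without scrambled array 3 Wnt targets gave 1 rise, and without scrambled array 1 or 3 NRF2 targets gave 1 fall. Under the first planned rule of the highest mean the medians were 0.16 for hypoxia and glycolysis and 0.021 for ATF4 targets. Immediate early genes gave 0 to 3 rises and 1 to 4 falls and p53 targets 2 to 5 rises and 3 to 4 falls over the 6 arrays left out in turn. Among 14 Wnt target genes 3 rose and 2 fell (camera adjusted p = 0.421), with Nkd2 (1.56 ± 0.096) and Sp5 (0.51 ± 0.11) higher and Rnf43 (-1.18 ± 0.19) and Myc (-0.59 ± 0.11) lower. Of 13 secreted Wnt antagonists and destruction complex genes 3 rose, Sfrp2 (1.08 ± 0.32), Sfrp5 (0.60 ± 0.13) and Sfrp4 (0.33 ± 0.094), and 0 fell (camera adjusted p = 0.266), and Sfrp1 differed by 0.34 with an adjusted p = 0.0568. Of 11 NRF2 target genes 6 rose and 2 fell (median 0.55; camera adjusted p = 0.0976, but 0.0051 with the spike-in covariate and 0.048 without X-linked genes), with the glutathione transferase Gsta4 (3.56 ± 0.19), the cystine transporter Slc7a11 (1.24 ± 0.13) and Srxn1 (0.87 ± 0.083) higher and Gclm (-1.01 ± 0.097) lower. ATF4 targets gave 4 rises and 4 falls of 15 (median -0.071, mean 0.15, with camera on the lower side, adjusted p = 0.945), such as Chac1 (1.66 ± 0.14), Cth (0.96 ± 0.11) and Shmt2 (-0.48 ± 0.082). Among 13 ER chaperones 1 rose, Sdf2l1 (0.62 ± 0.14), and 3 fell, Dnajc3 (-0.86 ± 0.080), Dnajb9 (-0.77 ± 0.14) and Manf (-0.59 ± 0.16), with a camera adjusted p = 0.629. The hypoxia and glycolysis list gave 3 rises and 4 falls of 16 (median -0.041, mean 0.10, with camera on the lower side, adjusted p = 0.942), with Egln3 at 1.54 ± 0.13, Car9 at 0.58 ± 0.14, Hk2 at 0.40 ± 0.097 and Pfkl at -0.32 ± 0.085. FGF/ERK response genes gave 2 rises, Etv1 (0.85 ± 0.12) and Etv4 (0.72 ± 0.17), and 3 falls of 10, including Phlda1 (-0.73 ± 0.12) and Fosl1 (-0.77 ± 0.17), with a camera adjusted p = 0.942. Of 12 immediate early genes 2 rose, Fos (0.36 ± 0.077) and Egr2 (0.37 ± 0.11), and 3 fell, including Jun (-1.32 ± 0.093) and Ier2 (-0.34 ± 0.11), with a camera adjusted p = 0.44. Among 8 CDK inhibitors and senescence genes 0 rose and 3 fell, Cdkn2a (-0.58 ± 0.091), Rbl2 (-0.42 ± 0.12) and Cdkn2b (-0.31 ± 0.076), and Rbl1 differed by -0.88 with an adjusted p = 0.0583 (list adjusted p = 0.44). Of 16 p53 targets, in a line said to lack p53, 4 rose, such as Trp53inp1 (0.56 ± 0.087), and 3 fell, Ei24 (-1.01 ± 0.16), Sesn1 (-0.75 ± 0.10) and Bax (-0.66 ± 0.11), with a list adjusted p = 0.71. Several of these calls rested on single arrays or settings. Those of Sfrp2, Sfrp4, Egr2, Ier2, Cdkn2b, Rbl2, Manf and Pfkl were lost without scrambled array 1, 2 or 3, that of Hk2 without scrambled array 1 or 3, that of Car9 without scrambled array 1, and those of Sp5 and Fos without scrambled array 3. Sfrp2 was also not called without Sox2 shRNA array 2 or 3, Egr2 without Sox2 shRNA array 3, and Sfrp4 and Egr2 with median centring of each array. With the highest mean Dnajc3 (-0.12, with probe sets down to -1.43), Sesn1 (-0.40), Shmt2 (-0.23), Pfkl (-0.15) and Ier2 (-0.34) were not called and Rbl2 turned to 0.11. Sesn1 was not called without _x_at and _s_at probe sets either, nor Ier2 with the largest variance. With the spike-in covariate the calls of Myc, Sp5, Sfrp4, Sfrp5, Shmt2, Sdf2l1, Dnajb9, Manf, Car9, Pfkl, Etv4, Phlda1, Fosl1, Fos, Egr2, Ier2, Cdkn2a, Rbl2, Cdkn2b, Ei24 and Bax were lost. Rbl1 was called lower without Sox2 shRNA array 1 (-0.46, limma adjusted p = 0.0054) or array 2 (-1.15, 0.026), with array weights (-0.52, 0.022) and with the largest variance (-1.39, 0.032), but was at 0.20 with the spike-in covariate. Sfrp1 was called higher without Sox2 shRNA array 1 (0.21, limma adjusted p = 0.0496) and with the largest variance (0.60).

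Most markers of other cell types did not pass the limma threshold. None of their lists passed camera with all arrays, where the adjusted p was 0.324 for macrophages and leukocytes, 0.378 for osteoclasts, 0.193 for endothelium and for epithelium, and 0.0976 for neural cells and for skeletal muscle. Their medians lay between 0.10 for epithelial and 0.25 for skeletal muscle genes. Of 14 macrophage and leukocyte genes 2 rose, Csf1r (0.76 ± 0.084) and Adgre1 (0.36 ± 0.12), and 1 fell, Cd14 (-0.83 ± 0.14). The 2-fold changes on these lists came down to 1 gene, the epithelial keratin Krt19 (2.31 ± 0.13). Krt7 (0.48) and Krt8 (0.34), 2 more of 10 epithelial genes, rose as well. The neural genes Nes (0.76), Stmn2 (0.48) and Tubb3 (0.32) made 3 rises of 11, Des (0.55) and Tnnt1 (0.28) 2 of 12 for skeletal muscle, Mmp9 (0.49) 1 of 7 for osteoclasts, and Flt1 (0.48) 1 of 10 for endothelium, with 0 falls on these 5 lists. The other members chosen by the rule did not pass, with limma adjusted p from 0.0506 for Kdr (0.50) to 0.233 for Ocln (0.13), and Laptm5, Nefm, Robo4, Acta1, Tnnt3, Tnfrsf11a, Calcr, Oscar and Cdh5 differed by 0.19 to 0.35. Adjusted over the list alone the counts were equal, except for 1 rise and 1 fall of leukocyte genes and 1 rise of skeletal muscle genes. With single arrays left out the rises ranged from 1 to 5 for skeletal muscle (5 without Sox2 shRNA array 3), from 1 to 4 for leukocytes (4 without Sox2 shRNA array 2) and from 1 to 3 for endothelium (3 without that array). They were 1 for neural genes without scrambled array 1 or 3, 1 for epithelial genes without scrambled array 3 and 2 for osteoclasts without Sox2 shRNA array 1, and 1 leukocyte gene rose without scrambled array 1, 2 or 3. Without Sox2 shRNA array 1 the medians were 0.084 for osteoclasts, 0.12 for endothelium and 0.16 for skeletal muscle, and without Sox2 shRNA array 3 the skeletal muscle list passed camera (median 0.40, adjusted p = 0.031). The calls of Adgre1 and Tubb3 were lost without scrambled array 1, 2 or 3, those of Tnnt1, Krt8 and Stmn2 without scrambled array 1 or 3, that of Krt7 without scrambled array 2 or 3, those of Tubb3 and Tnnt1 without Sox2 shRNA array 2, and that of Tnnt1 without Sox2 shRNA array 3. With the highest mean or the largest variance Krt8 (0.26), Stmn2 (0.51), Tnnt1 (0.28) and Adgre1 (0.36) were not called and Laptm5 was (0.46), and Krt8 was not called without _x_at and _s_at probe sets. Tnnt1 and Adgre1 were not called with median centring of each array, nor Tnnt1 with array weights or another variance model, and with the spike-in covariate Cd14, Flt1, Krt7, Krt8, Stmn2, Tubb3, Tnnt1 and Adgre1 were not called. Kdr, Laptm5 and Robo4 were called higher without Sox2 shRNA array 2, Acta1 and Nefm without array 3 and Tnfrsf11a without array 1, and the last 3 also with array weights.

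The array control probe sets separated the groups. The 18 probe sets of the bacterial and phage spike-ins bioB, bioC, bioD and cre, which are added to each hybridisation, had means of 0.24, -0.13 and -0.22 in scrambled arrays 1 to 3 and of 1.26, 0.58 and 0.56 in the arrays labelled Sox2 shRNA. That is a difference of 0.84 (exact permutation p = 0.1, two-sided, the smallest that 3 arrays against 3 can give). The 3' minus 5' difference of the Actb control probe sets, a measure of RNA integrity and of labelling, was higher by 0.94 (0.93 ± 0.54 against -0.0098 ± 0.32, SD, n = 3; exact permutation p = 0.1) and reached 1.55 in Sox2 shRNA array 1. For Gapdh it differed by 0.29 (exact permutation p = 0.3). Left out, Sox2 shRNA array 1 gave 2695 higher and 3135 lower genes by limma, with 361 and 362 at least 2-fold, and a median of 2.41 for the interferon list, -0.60 for mitosis and -0.49 for cholesterol synthesis. With the mean spike-in level as a covariate, chosen after seeing the data, limma called 859 higher and 1049 lower genes, 405 and 277 of them at least 2-fold, and kept 500 of the 832 genes changed at least 2-fold.

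**Figure D3:**
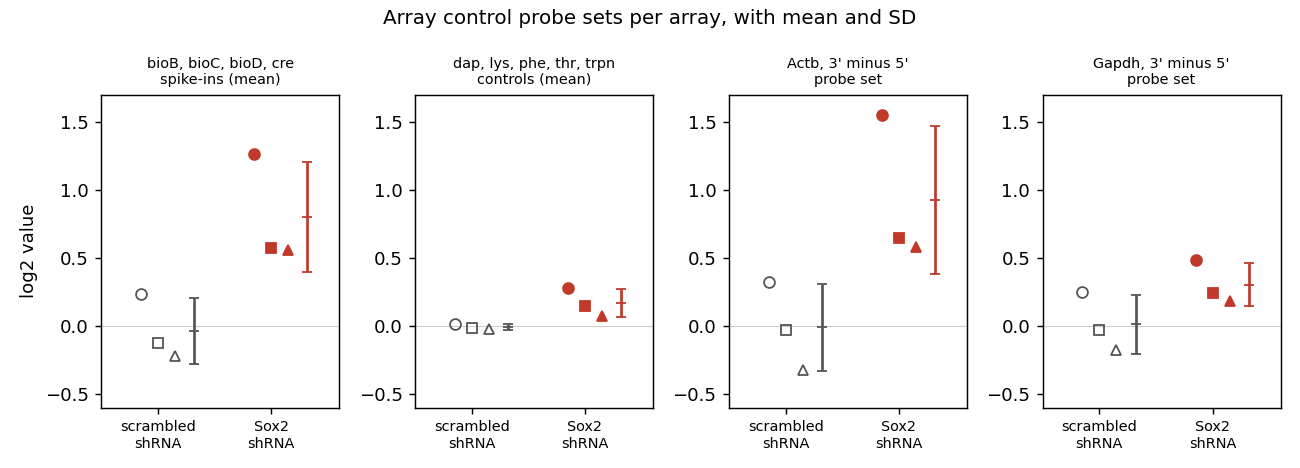
Log2 value (y axis) of 4 array control measures per array, with open grey symbols for scrambled arrays, filled red symbols for arrays labelled Sox2 shRNA (circle, square and triangle for arrays 1, 2 and 3), and the mean ± SD of each group, n = 3, to the right. The arrays labelled Sox2 shRNA lie above all scrambled arrays in the first 3 panels, by 0.84, 0.17 and 0.94 in the mean, and the groups overlap for Gapdh, with a difference of 0.29.

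Ontology terms among the genes changed at least 2-fold named similar groups. Of 340 higher genes with a term, 25 belonged to the immune response where 4.63 were expected (Fisher's exact test, adjusted p = 1.65e-08), including C3, Oas1a, Ccl17, Cxcl12 and Il6. The term for extracellular matrix held 14 higher genes where 2.90 were expected (adjusted p = 9.2e-04), and that for insulin-like growth factor binding 5 where 0.59 were expected (adjusted p = 0.040). Those 5 genes, of which all but Igfbp3 were chosen after their values were seen, were Igfbp3, Igfbp7, Igfbp5, Igfbp6 and Htra1. Of 449 lower genes with a term, 23 belonged to mitosis where 6.44 were expected (adjusted p = 1.9e-04), among them Cdk1 and Ube2c. In all 15 terms passed for higher and 5 for lower genes. Without Sox2 shRNA array 1 the terms for lower genes came to 1 and those for higher genes to 19.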

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

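The tests of RNA quality and of the spike-in shift, of the size of the fall of X-inactivation escape genes, of the shares of lower genes per chromosome and of the hairpin were chosen after the results they bear on were seen, as were the random range for other X-linked genes and the bootstrap interval for chromosomes. The other tests in this part are recorded as written before their own values were seen. Those on Xist and on the interferon genes were still written for a fall and a rise already seen. The Sox2 probe set was not lower in the arrays labelled Sox2 shRNA, and whether it lay above background is unknown, so each direction rests on that label. Signals outside the gene comparison were higher in all 3 arrays labelled Sox2 shRNA than in all 3 scrambled arrays, by 0.838 (log2) for the bioB, bioC, bioD and cre spike-ins, by 0.173 for the dap, lys, phe, thr and trpn controls and by 0.936 for the 3' minus 5' difference of Actb. Among the 1070 probe sets that name several genes or none, which were not used for genes, 27 were at least 2-fold higher and 28 at least 2-fold lower (limma adjusted p under 0.05).

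Xist fell by 5.94 log2 units and Sox2 was not lower in the arrays labelled Sox2 shRNA. Cells of different sex with a kept Y chromosome are argued against by the 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, with a median difference of 0.11 and the highest at 0.35, and loss of X silencing by an X-linked median 0.13 below the autosomal one (-0.13). Loss of the inactive X chromosome stays open, because the 4 measured escape genes Kdm6a, Kdm5c, Eif2s3x and Ddx3x lay 1.21 below all genes in the median (-1.21), as it needs, but the other X-linked genes were not near 0, at -0.12 where 1000 random sets of genes as many as those on the X chromosome reached -0.075. Loss of 1 of 2 copies is not the whole size of the fall for Eif2s3x and for the probe set average of Kdm6a. Their 95% intervals ended at -1.42 and -1.29, below the -1 that it allows, while those of Ddx3x (-0.70) and Kdm5c (-0.40) lay within it. The 2 probe sets of Eif2s3x lay at -1.74 and -1.69. Those of Kdm6a lay at -2.06 and -1.07, the latter close to -1. Another cell line of the same sex, or a subclone, was not tested and remains possible.

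The wide change across genes came with a difference in array controls. In the spike-ins Sox2 shRNA array 1 lay 2.15 times as far from the scrambled arrays as arrays 2 and 3. In the 832 genes changed at least 2-fold it lay a median of 1.14 times as far (upper quartile 1.39). Those genes were chosen by limma on the same arrays, which favours genes whose arrays agree. The ratio therefore does not decide on a shift of array signal as their whole cause. The spike-ins are added to each hybridisation and so do not measure RNA yield. A part played by RNA quality cannot be told apart from the groups, as all 3 arrays were shifted and leaving array 1 out left 115% as many genes. Copy number is open, as chromosome 10 had the lowest autosome median, -0.19 relative to all genes (bootstrap interval -0.27 to -0.12, which spans the limit of 0.2 in size set for it), and 8 of 20 chromosomes had medians outside the range of 1000 random gene sets. Of the changed genes of chromosome 10, 77.3% were lower, against 53.3% on the other autosomes, but this restates the median for which that chromosome was picked and does not decide on fewer copies of it. Genes named above that lie on chromosome 10 include Ccn2, Cdk1, Phlda1, Sesn1, Shmt2 and Pfkl, which fell. Dcn, Col6a2 and Egr2, on the same chromosome, rose. Whether the chromosome accounts for any of these falls was not tested. The share that was lower differed from that of other autosomes on 15 of 20 chromosomes (two-sided Fisher's exact test over genes, which are not independent, adjusted p under 0.05), with 8 having a larger share and 7 a smaller one, such as 84.3% on chromosome X and 28.6% on chromosome 7, and DNA was not measured. The X-linked genes named above include Bgn, Phex and Pola1, and whether the X chromosome accounts for their falls was not tested.

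The 10 splits of 3 against 3 arrays are too few for a share under 0.05. The real split gave 5090 genes by limma and the highest of the other splits 0 (151 at an unadjusted p under 0.05), so that 1 of the 10 gave as many. For genes changed at least 2-fold the counts were 832 and 0 (2 at an unadjusted p), again with 1 of 10. For ontology terms the counts were 20 and 0 (0 at an unadjusted Fisher p). The other splits had 0 genes changed at least 2-fold to enter, so no term could pass in them. The count of terms there adds nothing to that of the genes. For gene lists the counts were 8 and 8, with 2 of the 10 splits giving as many. All other splits called lists, from 3 to 8, so the number of lists called does not set the real split apart. Each other split has 2 arrays of 1 label and 1 of the other on each side. It thus keeps part of the group difference, for which camera can also call lists. That number therefore cannot decide whether the list calls are due to the groups.

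Genes of the interferon response were higher in the arrays labelled Sox2 shRNA. RNA of leukocytes is argued against by a median of 0.20 over the 14 leukocyte genes, none of them on the interferon list. Of these, limma called 2 higher and 1 lower, and 0 were at least 2-fold higher. A shift of array signal, as the spike-ins measure it, is argued against as the whole cause. The list median was 2.06 in Sox2 shRNA array 1 and 2.41 in arrays 2 and 3, a ratio of 0.85 where the spike-ins gave 2.15. A response to the Sox2 hairpin itself, rather than to a loss of Sox2, cannot be told apart from the groups, since 1 hairpin was used. The 95% interval of the Sox2 difference began at -0.052. A probe set at background could not show a fall, so that interval does not decide the question. A change that follows loss of Sox2 stays open, untested.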

How the results depend on the processing

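The spike-in covariate and the fit without X-linked genes were chosen after seeing the data, as was the exchange of the first planned rule, the highest mean, for averaging, and the other settings before. Quantile normalization and both filters on dim probe sets were not run, because centred values hold no common distribution or level, and without levels it is unknown which genes lay above background. The other deposited table gave the same values. Sox2 stayed uncalled and positive in all settings, between 0.11 and 0.38 with single arrays left out. Leaving out each array gave 1155 to 2695 higher and 1944 to 3135 lower genes, 342 to 369 and 362 to 563 at least 2-fold, 4 to 6 higher and 3 lower lists, and 11 to 19 higher and 1 to 5 lower terms. At an adjusted p under 0.01 there were 1058 higher and 1848 lower genes, at 1.5-fold 875 and 1568, and with limma's treat against 2-fold 137 and 60. The lower genes came to 1900 with the probe set of highest mean, and those at least 2-fold lower to 935 with that of largest variance. Both rules favour probe sets by their difference. The spike-in covariate, which largely follows the groups and leaves fewer degrees of freedom, gave 859 higher and 1049 lower genes and 277 at least 2-fold lower. It kept 1708 of the 5090 calls and 500 of the 832 at least 2-fold, while 829 of these 832 had the same direction. Camera with an estimated correlation called 0 lists higher and 0 lower, with 3 lists at an unadjusted p under 0.05, and fry 20 and 5. Without a size threshold 26 terms passed for higher and 49 for lower genes. The interferon, chemokine, MHC class I, mesenchymal surface, mitosis and cholesterol lists passed camera with its preset correlation in all 16 other settings, DNA replication in 14 and the chondrocyte list in 10. Of 150 named genes 82 kept their direction and call in all settings and 11 changed sign in 1, 4 of them called with all arrays. With the highest mean these were the called Phex (0.29) and Rbl2 (0.11) and the uncalled Runx2 (0.70), whose probe sets disagree. With the spike-in covariate they were the called Manf (0.018) and Adgre1 (-0.0096) and the uncalled Lin28a (-0.083), Rbl1 (0.20), Calcr (-0.18), Oscar (-0.21), Robo4 (-0.11) and Cdh5 (-0.062), where the cause was not tested. Beside those that changed sign, calls lost among named genes numbered 40 with the spike-in covariate, 12 with the highest mean, 23, 17 and 23 without scrambled array 1, 2 or 3 0, 6 and 3 without Sox2 shRNA array 1, 2 or 3, and 0 to 5 in the other settings. The replicate numbers did not pair the arrays, with correlations of deviations of 0.12, -0.025 and 0.17 for numbers 1 to 3 and -0.23 to 0.16 for unlike numbers. The replicate block gave 2136 higher and 2784 lower genes, and under it Sox9 and Tnnt1 were not called and Rbl1 and Kdr were.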

Other observations

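The test below was chosen after the values were seen, as were the genes named in this part. Beyond the lists, the arrays labelled Sox2 shRNA had higher Lcn2, which binds siderophores (4.20 ± 0.24), podoplanin, Pdpn (3.80), the aldehyde dehydrogenases Aldh3a1 (3.04) and Aldh1a1 (2.63), the alarmin Il33 (2.88), the cadherin Cdh11 of mesenchymal cells (3.17) and the necroptosis kinase Ripk3 (2.67). Cd34, a surface protein of progenitor cells, was lower (-2.07), as were Foxc1 (-1.92), the kinase Sgk1 (-2.09) and the deacetylase Sirt1 (-1.87), the last 2 on chromosome 10. Rb1, 1 of the genes this line is said to lack, differed by -0.59 and Trp53 by 0.16, and the levels behind both are unknown.

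The imprinted genes Asb4 (-2.10), Grb10 (-1.83), Peg3 (-1.76) and Impact (-1.70) were at least 2-fold lower and Dcn (5.77) at least 2-fold higher, with smaller rises of Dlk1 (0.62) and Igf2 (0.57). A hypothesis that imprinted genes changed more often than others was tested on 35 of them. At least 2-fold changes were found in 14.3%, against 6.28% of other genes (two-sided Fisher's exact test, p = 0.066), which leaves it undecided.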
